A study of Mus musculus with 18 samples.

How the data were processed

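The samples are livers of female C57BL/6 mice given peanut oil or TCDD by gavage, sequenced as poly-T selected mRNA. They form 6 groups of 3 mice: 3 genotypes, each with vehicle and with TCDD at 100 µg/kg. Per the labels, doses came every 4 days and livers were taken at day 92, and RNA for the libraries came from 10 mg of liver with an RNA integrity number above 6.8. The genotypes are named here WT (mice with a floxed but intact Ahr gene), dHep (AHR, the aryl hydrocarbon receptor, deleted in hepatocytes) and dHSC (AHR deleted in hepatic stellate cells). Libraries were made with a NEBNext Ultra RNA kit per the labels' protocols. Each library is 1 mouse and is named by its group and the mouse number in its label. No mouse number occurs in more than 1 group, so the labels pair no mice.

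Each deposited file holds raw read counts per gene for 1 library, as whole numbers without a header, for 55536 Ensembl gene identifiers. Per the submitters' processing notes, the tools used were FastQC 0.11.9, HISAT2 2.1.0, HTSeq 0.11.3 and DESeq2 1.22.2, and the genome build was GRCm38. The notes give no counting settings. The deposited counts were checked as unnormalised: their totals differ between libraries, from 12706490 to 27240877. The identifiers are the same set as those of GENCODE M21, from which gene names, types and GRCm38 coordinates were taken, and 55450 of them have a name. The counting was checked against the annotation. Of 533 protein-coding genes whose exons are clear of all other exons but which lie wholly inside other genes, 531 had no count in any library, against 10.7% of the 11858 genes clear of all other genes. Of the 379 such genes that lie only inside genes on the opposite strand, 378 had no count. Reads over the span of more than 1 gene were thus apparently left uncounted on either strand. Genes overlapped by others therefore lost a share of their reads that the counts do not give. Counting by gene span would also take in reads over introns and from the opposite strand, and the notes do not say whether such reads were counted.

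Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with its default settings, which kept 14835 genes, and libraries were scaled by TMM. All 18 libraries were fitted in 1 model with a mean per group. Groups were compared by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The 7 comparisons were TCDD against vehicle in each genotype, the difference of that response between dHep and WT and between dHSC and WT, and each deleted genotype against WT in vehicle. Levels are given as CPM, computed from the deposited counts after TMM scaling, as mean ± SD over the 3 mice of a group. Differences are given on the log2 scale with their standard error from the fit. The common dispersion was 0.200, a biological coefficient of variation of 0.448.

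Before the data were examined, the samples, the tests, the alternatives, the rule for named genes and 34 gene lists with 516 genes were fixed. By that rule the named genes are the 12 with the largest rise and the 12 with the largest fall in each TCDD comparison, the 10 each way in each response difference and the 8 each way in each vehicle comparison. They come from the called genes with a mean of at least 1 CPM and a symbol other than a predicted-gene name. In the TCDD and vehicle comparisons every library of one group also had to lie beyond every library of the other. Members of the fixed lists serve as further examples, and Ahr was named in advance. Of the 516 list genes, 42 were not tested, and 1 was matched by an older symbol. For each list the called members were counted over all genes tested and adjusted over the list alone. Lists were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, and adjusted over the 34 lists of a comparison. They were tested again with an estimated correlation and with fry. A preset correlation takes little account of genes that vary together between mice.

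The other settings chosen then were RLE scaling, no filter on low counts, at least 1 CPM in 3 libraries, a fit of only the groups of the comparison, DESeq2 1.42.0, a change of at least 2-fold, leaving out each library in turn, an estimated correlation, and fry. Chosen after seeing the data were a fit with the log2 percent of counts outside protein-coding genes as a covariate, a fit without the 5 libraries in which that percent exceeds 2, and a fit with 3 sets of 6 consecutive mouse numbers as a block. A list of 12 skeletal muscle genes was also chosen after seeing the data. When the lower group of a named gene holds no counts, the fold is given as at least the ratio to a floor of 3 counts over the group. When it holds 1 to 3 counts, the ratio is given with its 95% exact Poisson interval. Intervals and floors cover only the counting error of the lower group and leave out variation between mice. PCR copies were not identified, so the counting error itself may be larger. Fitted differences of such genes depend on the prior count.

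The tests were run on simulated counts with 200 genes changed in the TCDD group of each genotype, 50 at each fold size. In the WT comparison edgeR called 6% of the genes changed 2-fold, 40% at 4-fold, 76% at 8-fold and 74% at 16-fold, with 1 false call among 99 calls. In the dHep comparison the shares were 0%, 36%, 80% and 90% with 3 false calls among 106, and in dHSC 4%, 46%, 76% and 84% with 3 false calls among 108. For the dHep and WT response difference, scored on the genes changed in WT, they were 0%, 24%, 54% and 70% with 5 false calls among 156. DESeq2 made 38 false calls among 161 in the simulated WT comparison, 39 among 160 in dHep, 23 among 148 in dHSC and 40 among 234 for the response difference. In the simulated WT comparison camera found the list that was shifted, and 2 of 200 random lists fell below 0.05. Simulated genes varied independently of each other, while real genes can vary together between mice. The false call rates of genes and lists therefore need not hold for the deposited counts.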

Results

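Liver RNA of 18 female mice was counted per gene, 3 mice in each of 6 groups. WT, dHep and dHSC mice had vehicle or TCDD, a dioxin that activates the transcription factor AHR. The question named in the series title is whether TCDD activates liver myofibroblasts, the cells that lay down scar matrix, through AHR in hepatocytes. Total counts ran from 12706490 in dHSC TCDD replicate 6 to 27240877 in dHep vehicle replicate 3. Genes and positions are given on GRCm38.

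Ahr, the gene targeted in both deletions (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038), had similar levels in all groups. Its mean was 51.5 ± 18.7 CPM (SD, n = 3) in WT vehicle, 51.5 ± 6.21 in WT TCDD. It was 38.0 ± 16.3 in dHep vehicle and 61.6 ± 32.9 in dHep TCDD. It was 39.4 ± 6.44 in dHSC vehicle and 47.4 ± 20.997 in dHSC TCDD. By library it was 32.7, 51.8 and 70.0 CPM in WT vehicle replicates 1, 7 and 13, and 56.6, 53.4 and 44.6 in WT TCDD replicates 2, 8 and 14. It was 56.8, 28.1 and 29.1 in dHep vehicle replicates 3, 9 and 15, and 94.9, 60.8 and 29.0 in dHep TCDD replicates 4, 10 and 16. In dHSC it was 45.5, 40.003 and 32.7 in vehicle replicates 5, 11 and 17, and 58.3, 60.8 and 23.2 in TCDD replicates 6, 12 and 18. None of the 7 comparisons called it, with log2 differences of 0.00 for TCDD in WT, 0.69 in dHep, 0.27 in dHSC, and -0.44 for dHep and -0.38 for dHSC against WT in vehicle. The labels do not give the deleted part of the gene, and counts over the whole gene need not fall when part of it is removed, so this level checks no label.

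Of the 18 libraries, 5 stood apart from the rest on the first principal component, which held 38.3% of the variance. They are dHep vehicle replicates 9 and 15, dHep TCDD replicate 16, dHSC vehicle replicate 17 and dHSC TCDD replicate 18. Their scores ran from 62.1 to 126 and those of the others reached at most 36.8. The same 5 had 2.20% to 4.25% of counts outside protein-coding genes, and the others at most 1.76%. In dHSC TCDD replicate 18, mitochondrially encoded genes took 28.4% of counts. No WT library is among the 5. WT vehicle replicate 1 held 1720 CPM summed over 12 skeletal muscle genes, against at most 9.89 CPM in any other library.

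**Figure D1:**
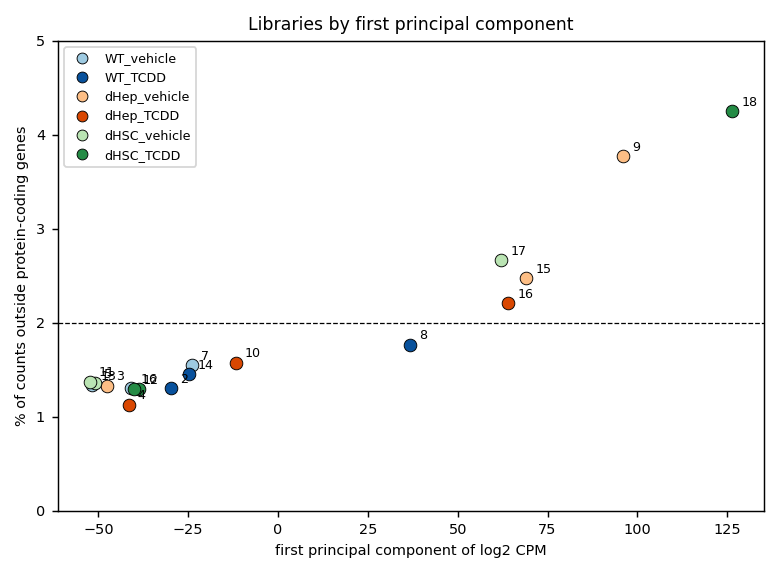
Each point is 1 library, numbered by mouse, at its first principal component score of log2 CPM (x) and its percent of counts outside protein-coding genes (y). The 5 libraries above the dashed line at 2% have scores from 62.1 to 126 and come from 4 of the 6 groups.

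In WT livers, which have AHR in all cells, TCDD raised 509 genes and lowered 289 of 14835 tested. The detoxifying enzymes under AHR control rose steeply. Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824) went from 15.4 ± 15.5 to 6430.2 ± 1690 CPM, a log2 change of 8.70 ± 0.92 (SE, n = 3, adjusted p = 4.56e-05). Hao1, the peroxisomal enzyme that oxidises glycolate (ENSMUSG00000027261, chromosome 2, 134497361 to 134554368), went from 179 ± 32.1 to 0.232 ± 0.211 CPM, a log2 change of -9.59 ± 0.78 (SE, n = 3, adjusted p = 4.52e-06). Some genes of neutrophils, B cells, scar-associated macrophages, chemokines and matrix breakdown rose, and some female-biased liver enzymes fell. Of these 6 lists, the scar macrophage list kept its call with an estimated correlation and the other 5 did not. By the rule that picked them, each named gene separated all 3 TCDD libraries from all 3 vehicle libraries, and folds of genes picked as the largest are inflated by that choice.

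The other genes among the 12 largest rises in WT were Col9a2, Hmx1, Pnliprp1, Nptx1, Cyp1b1, Ahrr, Amn, Apol7c, Mmp7, Gipc2 and Gpnmb, with log2 changes from 7.05 (Gpnmb) to 11.70 (Col9a2). Col9a2, a chain of the cartilage collagen IX, had 2 counts in all of WT vehicle and a mean of 149 CPM with TCDD, a ratio of 3926 (95% counting interval 1087 to 32415). Pnliprp1, a relative of pancreatic lipase, had 1 count in vehicle and a ratio of 1631 (interval 293 to 64403). The homeobox gene Hmx1, with no count in vehicle, was at least 326-fold higher. Nptx1, a secreted pentraxin best known from neurons, rose from 0.247 ± 0.0881 to 163 ± 63.5 CPM. Cyp1b1, another AHR-controlled cytochrome, rose by 9.19 ± 0.76 on the log2 scale, and Ahrr, the AHR repressor, by 8.03 ± 0.64. The largest falls, besides Hao1, were in Sult3a2, Sult3a1 and Sult2a7 (sulfotransferases), Cyp3a16 and Cyp3a41a (female-biased cytochromes), Irx1, Serpina1e, Mmd2, Lmod3, Ube2u and Car3. Sult3a2 had 1 count in WT TCDD against 36.1 ± 36.6 CPM in vehicle, a ratio of 2294 (interval 412 to 90593). Irx1, a homeobox gene, had 1 count and a ratio of 165 (interval 29.7 to 6528). Car3, a carbonic anhydrase abundant in liver, fell from 2553 ± 1523 to 52.9 ± 18.4 CPM. Lmod3, a muscle gene, had 19.3 CPM in WT vehicle replicate 1 and about 0.504 and 0.459 CPM in the other 2. Without replicate 1 its log2 change is -2.25 with an adjusted p of 0.269. It was also not called without TCDD replicate 2, 8 or 14, at adjusted p of 0.0886, 0.0753 and 0.107. Calls of Cyp3a16 and Cyp3a41a ended in 3 and 5 of the 6 fits that leave out 1 library, with adjusted p up to 0.0813 and 0.143. Those of the other 21 named genes held in all 6.

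Among the fixed lists, 9 of 12 tested AHR target genes rose in WT (11 adjusted over the list alone), and the list led all others (camera adjusted p = 9.03e-21; adjusted p = 0.000514 with an estimated correlation). They include Cyp1a2, from 1189 ± 826 to 16064 ± 3511 CPM. Also called were Tiparp, an AHR-induced ADP-ribosyltransferase, with a log2 change of 3.68 ± 0.37, and Nqo1, a quinone reductase, at 2.67 ± 0.33. Of 12 genes of infiltrating monocytes and scar macrophages 5 rose (8 adjusted over the list alone; camera adjusted p = 2.03e-09; adjusted p = 0.0198 with an estimated correlation), among them Gpnmb, Itgax at 2.99 ± 0.43 and Lgals3 at 3.05 ± 0.59. These 2 lists kept their call in WT with an estimated correlation, and no other list did. Of 9 neutrophil genes 7 rose (9 adjusted over the list alone) with a median log2 change of 5.08, such as the calgranulin S100a9 at 5.08 ± 0.97 and the chemokine receptor Cxcr2 at 5.29 ± 0.84 (camera adjusted p = 4.08e-12; adjusted p = 0.0688 with an estimated correlation). Of 7 B and plasma cell genes 4 rose (6 adjusted over the list alone), including Cd79b, part of the B cell receptor, at 2.54 ± 0.43 (camera adjusted p = 2.95e-07; adjusted p = 0.167 with an estimated correlation). Of 14 cytokine and chemokine genes 5 rose (11 adjusted over the list alone), with Cxcl2, which draws neutrophils, at 5.06 ± 0.95 and Ccl4 at 3.74 ± 0.74 (camera adjusted p = 1.27e-09; adjusted p = 0.0548 with an estimated correlation). Of 14 matrix turnover genes 6 rose (6 adjusted over the list alone), including the proteases Mmp12 at 5.01 ± 0.65 and Mmp13 at 6.34 ± 0.56 (camera adjusted p = 1.40e-09; adjusted p = 0.0548 with an estimated correlation).

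Of 17 NRF2 target genes, which answer oxidative stress, 5 rose in WT (9 adjusted over the list alone), with Srxn1 at 1.84 ± 0.33 and Abcc4 at 2.16 ± 0.41 (camera adjusted p = 6.35e-08; adjusted p = 0.0774 with an estimated correlation). The acute phase list was split: Saa1, Saa2, Saa3, Orm2 and Lcn2 rose, Saa1 by 4.63 ± 0.66, while Apcs fell by 2.01 on the log2 scale (camera adjusted p = 0.139). On the side of falls, 6 of 14 female-biased liver genes were lower (10 adjusted over the list alone) with a median of -1.98, Sult3a1 and Cyp3a44 among them (camera adjusted p = 4.06e-08; adjusted p = 0.0905 with an estimated correlation). Of 15 fatty acid and triglyceride synthesis genes 2 fell (6 adjusted over the list alone): Fasn, the fatty acid synthase, by 1.86 and Dgat2, which makes triglyceride, by 1.44 (camera adjusted p = 6.48e-05; adjusted p = 0.207 with an estimated correlation). Of 16 bile acid genes 2 fell, Cyp27a1 and the transporter Slco1a1 (camera adjusted p = 0.000396; adjusted p = 0.184 with an estimated correlation). Of 12 periportal hepatocyte genes Otc, Gls2 and Hal fell while Cdh1 rose (camera adjusted p = 0.000638; adjusted p = 0.246 with an estimated correlation). Fgf21, a liver hormone of fasting and stress, rose by 5.53 ± 0.85. Of the 84 list members called in WT, 40 kept their call whichever library was left out and 81 kept it with RLE scaling. The count of called genes was 445 without WT TCDD replicate 2, 463 without vehicle replicate 7, 463 without vehicle replicate 13 and 454 without TCDD replicate 14.

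Of the remaining lists in WT, 4 of 14 Kupffer and macrophage genes rose (median 0.54; camera adjusted p = 0.000664; adjusted p = 0.345 with an estimated correlation), as did 2 of 12 cholangiocyte genes, Prom1 and Epcam (1.35; 0.000678; 0.224 with an estimated correlation), and Asns of the unfolded protein response list (0.04; camera adjusted p = 0.672). T and NK cell genes (1.08; 0.000234; 0.246 with an estimated correlation) and cell cycle genes (1.13; 0.000450; 0.345 with an estimated correlation) leaned higher with 0 called. Hepatocyte identity genes (-0.58; 0.000736; 0.207 with an estimated correlation), glucose metabolism genes (-0.71; 0.00134; 0.224 with an estimated correlation) and cholesterol synthesis genes (-0.35; 0.0432; 0.618 with an estimated correlation) leaned lower with 0 called. Fatty acid oxidation genes leaned lower (-0.47; 0.0278; 0.531 with an estimated correlation) although Fgf21, their 1 called member, rose. Liver endothelial genes had Vwf higher and Lyve1 lower (camera adjusted p = 0.102), pericentral hepatocyte genes 1 higher and 1 lower (0.672), male-biased liver genes 2 higher and 1 lower (0.764), and the pancreas, fat and mesothelium list 1 lower, Cela1 (0.0185; 0.212 with an estimated correlation). With 0 called, camera gave 0.672 for CAR and PXR targets, 0.777 for retinoid metabolism, 0.430 for heme and iron, 0.234 for the circadian clock, 0.276 for erythroid and 0.0839 for mitochondrially encoded genes.

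**Figure D2:**
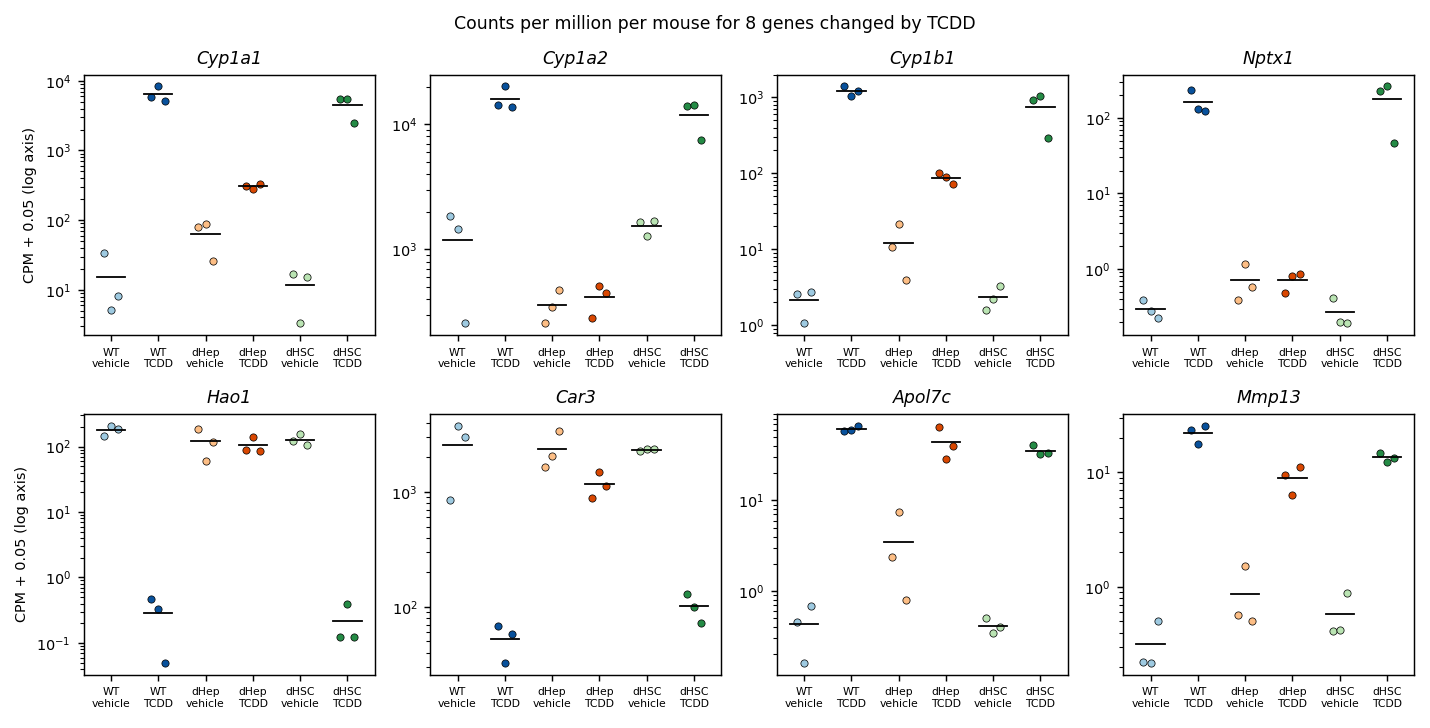
CPM on a log axis (0.05 added) of 8 genes, 1 point per mouse and a line at the mean of each group of 3. Cyp1a1, Cyp1a2, Cyp1b1, Nptx1, Hao1 and Car3 differ between vehicle and TCDD in WT and dHSC far more than in dHep, while Apol7c is at 44.4 CPM and Mmp13 at 8.92 CPM in dHep TCDD, between the dHep vehicle and the WT TCDD means.

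In dHep livers, which lack AHR in hepatocytes, TCDD raised 4 genes and lowered 6. Apol7c, an apolipoprotein L family gene (ENSMUSG00000044309, chromosome 15, 77524852 to 77533316), went from 3.46 ± 3.43 to 44.4 ± 18.3 CPM, a log2 change of 3.67 ± 0.59 (SE, n = 3, adjusted p = 0.0259). The collagenase Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331) went from 0.821 ± 0.578 to 8.92 ± 2.38 CPM, at 3.43 ± 0.48 (adjusted p = 0.00943). Adamdec1, a metalloprotease, rose by 2.24 ± 0.39 (adjusted p = 0.0471). The fourth, Gm8221, which lies near Apol7c on chromosome 15, rose by 3.62 ± 0.57 and is named after its values were seen, since the rule leaves out predicted-gene names. All 4 also rose in WT and in dHSC livers. Mup17, a major urinary protein gene, fell from 1696 ± 1359 to 29.0 ± 8.27 CPM at -5.87 ± 0.94. The other falls were the pseudogenes Mup-ps10 (-5.08 ± 0.82), Mup-ps12 (-4.70 ± 0.65) and Mup-ps14 (-4.28 ± 0.60), Lnx1, a ubiquitin ligase, at -3.12 ± 0.54, and Gm13775 (-3.52), likewise named after its values were seen. Mup17 and the Mup pseudogenes lie together on chromosome 4, between 61243577 and 61610983. Whether they fell separately or share 1 signal was not tested. Cyp1a1 was at 63.9 ± 33.2 CPM with vehicle and 307 ± 25.4 with TCDD (adjusted p = 0.473), and Cyp1b1 at 11.9 ± 8.69 and 87.4 ± 14.5 (adjusted p = 0.0909).

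Of the AHR target genes 0 passed in dHep and 4 passed adjusted over the list alone, Cyp1a1, Cyp1b1, Ahrr and Tiparp, all higher (camera adjusted p = 2.03e-07; adjusted p = 0.0565 with an estimated correlation). Matrix turnover had Mmp13 as its 1 called member (3 adjusted over the list alone; camera adjusted p = 3.02e-08; adjusted p = 0.123 with an estimated correlation). The other lists had no called member in dHep. The dHep groups hold 3 of the 5 libraries that stand apart, 2 with vehicle and 1 with TCDD. Without the 5, dHep vehicle is a single library assumed to vary like the other groups, so only log2 changes are given. They were 4.32 for Apol7c, 3.90 for Mmp13 and 1.99 for Adamdec1. The falls were smaller, at -4.20 for Mup17, -3.17 for Mup-ps10, -2.68 for Mup-ps12, -2.69 for Mup-ps14 and -2.61 for Lnx1. A fit of the dHep groups alone called 0 genes. The count was 0 without TCDD replicate 4, 2 without TCDD replicate 10, 3 without vehicle replicate 15 and 1 without TCDD replicate 16, and each of the 8 genes named by the rule lost its call in 3 to 5 of the 6 such fits (adjusted p up to 0.299).

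Whether the TCDD response depended on AHR in hepatocytes was tested by the difference of the dHep and WT responses, which called 127 genes: 52 with a higher and 75 with a lower log2 change in dHep. Hao1 kept its level in dHep livers (120 ± 60.9 CPM with vehicle, 105 ± 30.5 with TCDD), a difference of 9.39 ± 0.90 on the log2 scale (SE, n = 3, adjusted p = 8.30e-05). Cyp1a1 and Cyp1b1 had smaller log2 changes in dHep by -6.44 ± 1.02 (adjusted p = 0.00582) and -6.33 ± 0.82 (adjusted p = 0.00156). Both also had higher levels in dHep vehicle than in WT vehicle, without a call over all genes, and this baseline makes up part of the differences. Of the 12 AHR target genes 8 had a lower change in dHep (8 adjusted over the list alone, with Aldh3a1 passing as higher there on few counts), and this was the 1 list that kept its call with an estimated correlation (camera adjusted p = 8.35e-16; adjusted p = 0.00190 with an estimated correlation). Of the 8 calls, 3 held whichever library was left out: Ahrr, Cyp1b1 and Cyp1a1. Without the 5 libraries that stand apart 3 held, Ahrr, Cyp1b1 and Nqo1, and Cyp1a1 was at -6.81 (adjusted p = 0.0577).

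The other 9 genes with the largest higher differences were Sult3a2, Sult3a1, Irx1, Sult2a7, Dsg1c (a desmoglein), Cyp2c69, Serpina1e, Mmd2 and Susd4, from 5.03 to 8.78. The others with the largest lower differences were Pnliprp1, Col9a2, Nptx1, Gipc2, Pdzrn3, Col4a3, Fabp12 and Ahrr, from -6.28 to -14.65. The values of Pnliprp1, Col9a2, Sult3a2 and Irx1 rest on groups with 0 to 2 counts and depend on the prior count. Nptx1 was at 0.665 ± 0.414 CPM with vehicle and 0.668 ± 0.206 with TCDD in dHep. Fgf21 (-5.28 ± 1.09) and the chemokine Cxcl1 (-4.35 ± 0.94) were also called lower, and Fmo2, a female-biased monooxygenase, higher (2.28 ± 0.51). These 3 calls ended in 9, 8 and 10 of the 12 fits that leave out 1 library (adjusted p up to 0.0986, 0.123 and 0.161). They also ended without the 5 libraries that stand apart (adjusted p = 0.0635, 0.315 and 0.257). Neutrophil genes had a median difference of -3.95 with 0 called and 7 adjusted over the list alone (camera adjusted p = 1.26e-08; adjusted p = 0.261 with an estimated correlation). In vehicle the median of the neutrophil list was 1.58 higher in dHep than in WT, and this baseline enters the difference. B and plasma cell genes had a median difference of -2.35 with 0 called and 5 adjusted over the list alone (camera adjusted p = 1.58e-06; adjusted p = 0.261 with an estimated correlation). Without the 5 libraries that stand apart, 19 genes were called, 18 of them among the 127. The count was 66, 75 and 65 without WT TCDD replicates 2, 8 and 14, 80 and 55 without WT vehicle replicates 7 and 13, 67 and 65 without dHep TCDD replicates 4 and 10, and 51 without dHep vehicle replicate 9. Of these 20 named genes, the calls of Sult3a2, Sult3a1, Serpina1e and Col4a3 ended when some 1 library was left out, with adjusted p up to 0.0712, 0.0933, 0.0651 and 0.0834. Without the 5 libraries that stand apart 14 of the 20 calls ended (adjusted p up to 0.404), and those of Hao1, Nptx1, Gipc2, Pdzrn3, Cyp1b1 and Ahrr held. In that fit dHep vehicle is 1 library and dHep TCDD 2. Of the 14 log2 differences 11 moved by at most 0.70, while those of Col9a2, Col4a3 and Fabp12 went to -10.54, -5.42 and -5.11, so the lost calls do not show that the differences rest on the 5 libraries.

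Of the 509 genes higher in WT, 397 (78.0%) had a positive log2 change in dHep, with a median of 0.53 there against 2.48 in WT. Of the 289 lower genes, 215 (74.4%) had a negative one, with a median of -0.31 against -2.16. The WT medians are inflated by selection, and with genes near 0 counts at their bound the dHep median of the higher genes is 0.56. All 4 genes called higher in dHep were among those higher in WT (0.137 by chance), and 0 of the 6 lower ones were among those lower in WT (0.117 by chance). Across genes, which are not independent replicates, the log2 changes in WT and dHep had a Pearson r of 0.205 and a Spearman rho of 0.158.

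**Figure D3:**
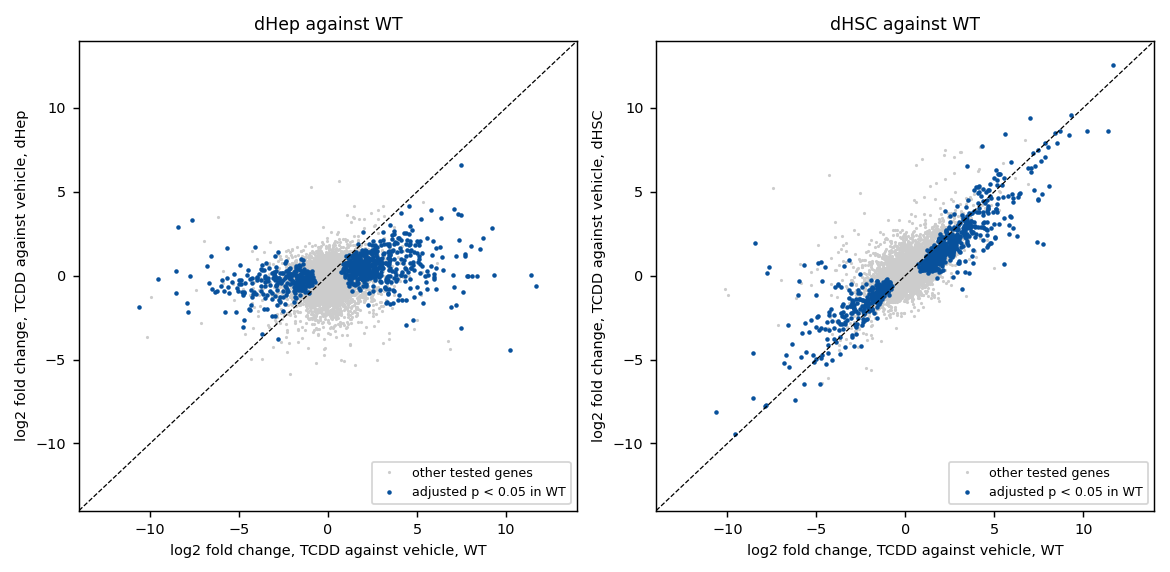
Each point is 1 of 14835 genes, with its log2 change with TCDD in WT (x) against that in dHep (left) or dHSC (right), genes called in WT in blue and equality dashed. The WT calls lie near 0 on the dHep axis, with medians of 0.53 and -0.31, and along the diagonal for dHSC, with medians of 1.76 and -1.38.

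In dHSC livers, which lack AHR in stellate cells, TCDD raised 254 genes and lowered 125, and most were genes changed in WT: 217 of the 254 (8.71 by chance) and 108 of the 125 (2.44 by chance). Cyp1a1 went from 11.7 ± 7.33 to 4503 ± 1780 CPM, a log2 change of 8.59 ± 0.92 (SE, n = 3, adjusted p = 8.41e-05). Hao1 went from 128 ± 24.2 to 0.164 ± 0.158 CPM, at -9.41 ± 0.79 (adjusted p = 7.07e-06). Of the genes higher in WT, 506 (99.4%) had a positive change in dHSC with a median of 1.76 (1.74 with genes near 0 counts at their bound). Of the lower ones 279 (96.5%) a negative change with a median of -1.38. The Pearson r across genes was 0.753 and the Spearman rho 0.659. The difference of the dHSC and WT responses called 0 genes with edgeR, where 233 had an unadjusted p under 0.05 and the smallest adjusted p was 0.431. DESeq2 called 3, all lower in dHSC.

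The named rises in dHSC besides Cyp1a1 were Col9a2, Nptx1, Ovol1, Pnliprp1, Hmx1, Adra2a, Cyp1b1, Ahrr, Apol7c, Gpnmb and Gipc2, from 6.20 (Gipc2) to 12.56 (Col9a2). Col9a2 had 1 count in dHSC vehicle and a ratio of 8178 (95% counting interval 1468 to 323020). Hmx1 had 2 and a ratio of 465 (interval 129 to 3839), and Pnliprp1 had 2 and a ratio of 453 (interval 125 to 3740). Ovol1, an epithelial transcription factor, and Adra2a, an adrenergic receptor, had none and were at least 76.1-fold and 40.2-fold higher. The falls besides Hao1 were Sult3a2, Sult2a7, Mmd2, Cyp3a16, Mup7, Irx1, Mup3, Serpina4-ps1, Nxph1, Ube2u and Serpinb1a, from -4.72 (Serpinb1a) to -8.12 (Sult3a2). Irx1 had 3 counts in dHSC TCDD and a ratio of 42.6 (interval 14.6 to 207), and Serpina4-ps1 had 2 and a ratio of 38.8 (interval 10.7 to 320). Of the 12 AHR target genes 7 rose (10 adjusted over the list alone; camera adjusted p = 3.18e-21; adjusted p = 0.000462 with an estimated correlation), and this was the 1 list in dHSC whose call held with an estimated correlation. Of the other lists, 4 neutrophil genes, 4 B and plasma cell genes, 4 matrix turnover genes and 4 scar macrophage genes rose (6, 7, 5 and 5 adjusted over the list alone; adjusted p = 0.227, 0.227, 0.0955 and 0.114 with an estimated correlation), and Fasn and Dgat2 fell. Of the 4 calls in each of these lists, 1, 0, 2 and 1 held whichever library was left out, and 2, 0, 4 and 2 held without the 5 libraries that stand apart. The calls of Fasn and Dgat2 each ended in 4 of 6 fits that leave out 1 library (adjusted p up to 0.131 and 0.155) and without the 5 (0.0726 and 0.212). Over all lists in dHSC, 14 of 40 calls held whichever library was left out and 18 without the 5. Mitochondrially encoded genes had a median of 0.64 in dHSC with 0 called, and dHSC TCDD replicate 18 is the library in which they take 28.4% of counts. A fit of the dHSC groups alone called 75 genes, and the count was 200, 169 and 238 without vehicle replicates 5, 11 and 17, and 214 without the 5 libraries that stand apart. Calls of Cyp3a16, Serpina4-ps1 and Adra2a ended in 6, 5 and 3 of the fits that leave out 1 library, with adjusted p up to 0.151, 0.156 and 0.0760. Without the 5 libraries the calls of these 3, Mup7 and Ube2u ended, with adjusted p up to 0.331. The log2 change was then 8.41 for Adra2a (8.46 with all libraries), -7.21 for Cyp3a16 (-7.27) and -5.11 for Ube2u (-4.83). It was smaller for Mup7, at -5.13 (-6.44), and Serpina4-ps1, at -4.32 (-5.06).

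The collagen and matrix genes, which bear on the question in the title, leaned higher with TCDD in all 3 genotypes, and in each the call of the list ended with an estimated correlation. In WT, 6 of 28 rose (13 adjusted over the list alone), none of them in every fit that leaves out 1 library: Col1a1, Col3a1, Col4a2, Lox, Thbs1 and Sparc. Col1a1, a chain of the main scar collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), went from 13.03 ± 12.2 to 71.6 ± 27.3 CPM in WT, a log2 change of 2.46 ± 0.54 (SE, n = 3, adjusted p = 0.0128). With 1 library left out the change of Col1a1 ran from 2.09 to 3.57, and its call ended without vehicle replicate 7 or 13 or TCDD replicate 14 (adjusted p up to 0.0667). Vehicle replicate 1, the library with high muscle genes, had 27.1 CPM of Col1a1 and the other 2 a mean of 6.02. It was at 9.09 ± 4.41 and 25.9 ± 1.40 CPM in dHep (log2 change 1.51 ± 0.53, adjusted p = 0.567) and 9.34 ± 3.42 and 37.9 ± 5.21 in dHSC (2.02 ± 0.54, adjusted p = 0.0622). The list's median was 1.06 in WT, 0.73 in dHep and 0.71 in dHSC, with 24, 26 and 24 of 28 genes above 0. Its camera adjusted p was 3.10e-08, 6.89e-11 and 1.94e-06, and the adjusted p was 0.223, 0.209 and 0.314 with an estimated correlation. In dHep 0 members passed (5 adjusted over the list alone) and in dHSC 1 did, Eln, elastin (5 adjusted over the list alone). The call of Eln ended in all 6 fits that leave out 1 library (adjusted p up to 0.201) and without the 5 libraries that stand apart (adjusted p = 0.315).

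The responses of this list were not shown to differ between dHep and WT: the median difference was -0.32, 0 members were called (0 adjusted over the list alone), and the camera adjusted p was 0.418. For dHSC against WT the median was -0.27 with 0 called (camera adjusted p = 0.0158; adjusted p = 0.553 with an estimated correlation). The dHep difference was at adjusted p = 0.00361 without WT vehicle replicate 1 and 0.0261 without WT TCDD replicate 8, both lower in dHep, and turned to higher at 0.711 without WT vehicle replicate 7. The dHSC difference ranged from 1.06e-07 without WT vehicle replicate 1 to 0.831 without WT vehicle replicate 7, and was also not called without WT TCDD replicate 2 (0.291) or 14 (0.289), WT vehicle replicate 13 (0.226), dHSC vehicle replicate 5 (0.293) or dHSC TCDD replicate 18 (0.291).

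Of 19 myofibroblast activation genes 3 rose in WT. Tnc, the wound matrix protein tenascin C (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), went from 0.873 ± 0.316 to 17.9 ± 3.28 CPM, a log2 change of 4.35 ± 0.53 (SE, n = 3, adjusted p = 0.000144). The others were the growth factors Tgfb2 at 3.43 ± 0.57 and Tgfb1 at 1.17 ± 0.32. Tgfb1 was not called with RLE scaling (adjusted p = 0.0555) or in 5 of the 6 fits that leave out 1 library (adjusted p up to 0.198). In dHSC Tnc and Tgfb2 rose, by 3.82 ± 0.52 and 3.10 ± 0.56. In dHep 0 passed over all genes, with Tnc at 2.56 ± 0.48 (adjusted p = 0.0757) the 1 gene past the threshold adjusted over the list alone, and Tgfb2 at 1.49 ± 0.54 (adjusted p = 0.599). The response differences of Tnc, -1.79 ± 0.67 for dHep (adjusted p = 0.408) and -0.53 ± 0.68 for dHSC, were not called. Acta2, the smooth muscle actin that marks myofibroblasts, was at 13.95 ± 15.4 and 5.88 ± 2.94 CPM in WT, 30.7 ± 46.1 and 15.1 ± 12.6 in dHep, and 4.99 ± 1.43 and 6.58 ± 4.15 in dHSC, with no call. Tpm2, a contractile protein, fell in WT by 5.005, with 379 CPM in WT vehicle replicate 1 and 11.7 and 7.63 CPM in replicates 7 and 13, and its call ended without vehicle replicate 1 or TCDD replicate 2, 8 or 14 (adjusted p up to 0.269). The list's median and mean in WT were -0.31 and -0.25 while camera gave a rise (adjusted p = 0.167), which passed without WT vehicle replicate 1 (0.0142). In dHep (median -0.12) camera also gave a rise at adjusted p = 0.0111, and in dHSC (median 0.65) at 0.00757, with adjusted p = 0.505 and 0.390 with an estimated correlation. The dHep call ended without dHep vehicle replicate 3 (0.498) or dHep TCDD replicate 16 (0.256), and was at 7.86e-08 without dHep vehicle replicate 9. The dHSC call ended without dHSC TCDD replicate 18 (0.0827). The response difference of the list was at 0.972 for dHep and 0.251 for dHSC, the latter at 0.00702 without WT vehicle replicate 13. Quiescent stellate cell genes had 0 of 15 called in any comparison.

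**Figure D4:**
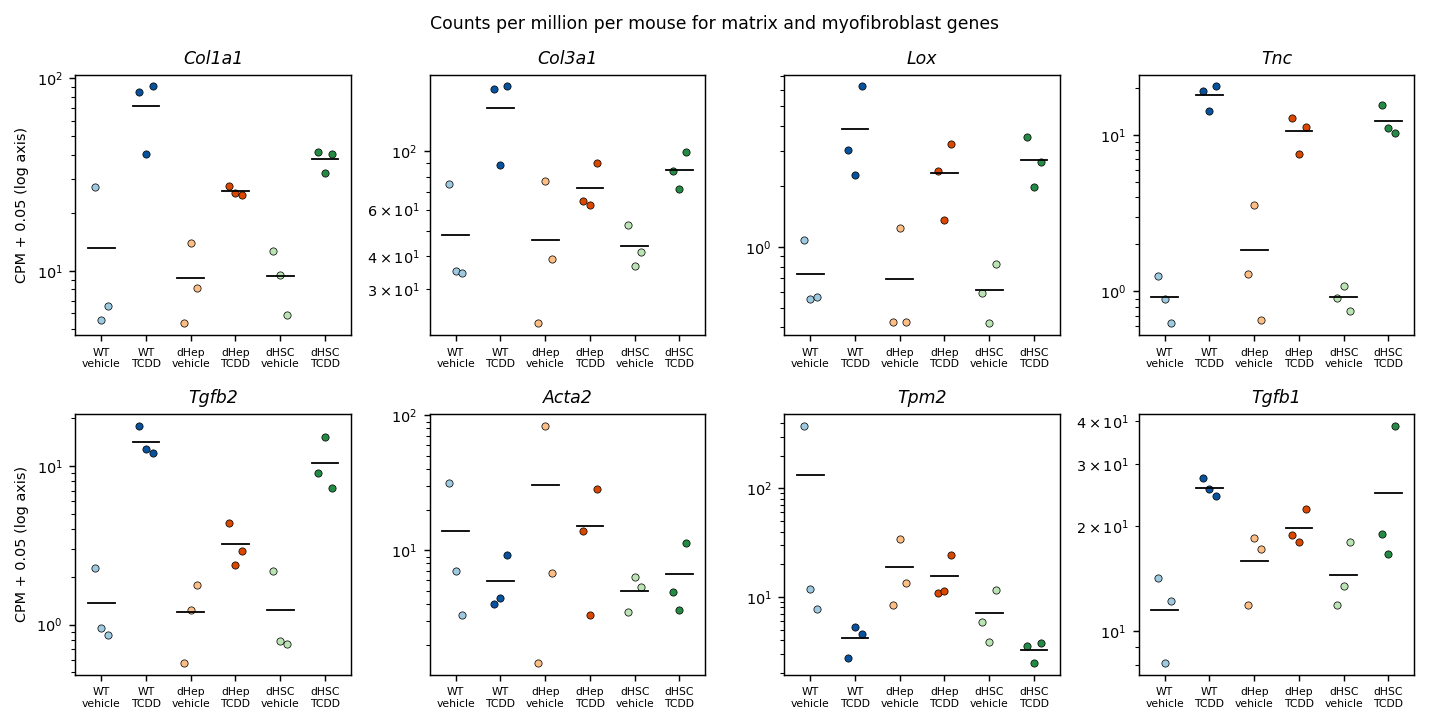
CPM on a log axis (0.05 added) of 8 matrix and myofibroblast genes, 1 point per mouse and a line at the mean of each group of 3. Col1a1 means are 71.6 CPM in WT TCDD, 25.9 in dHep TCDD and 37.9 in dHSC TCDD, and the Tpm2 value of 379 CPM is WT vehicle replicate 1.

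**Figure D5:**
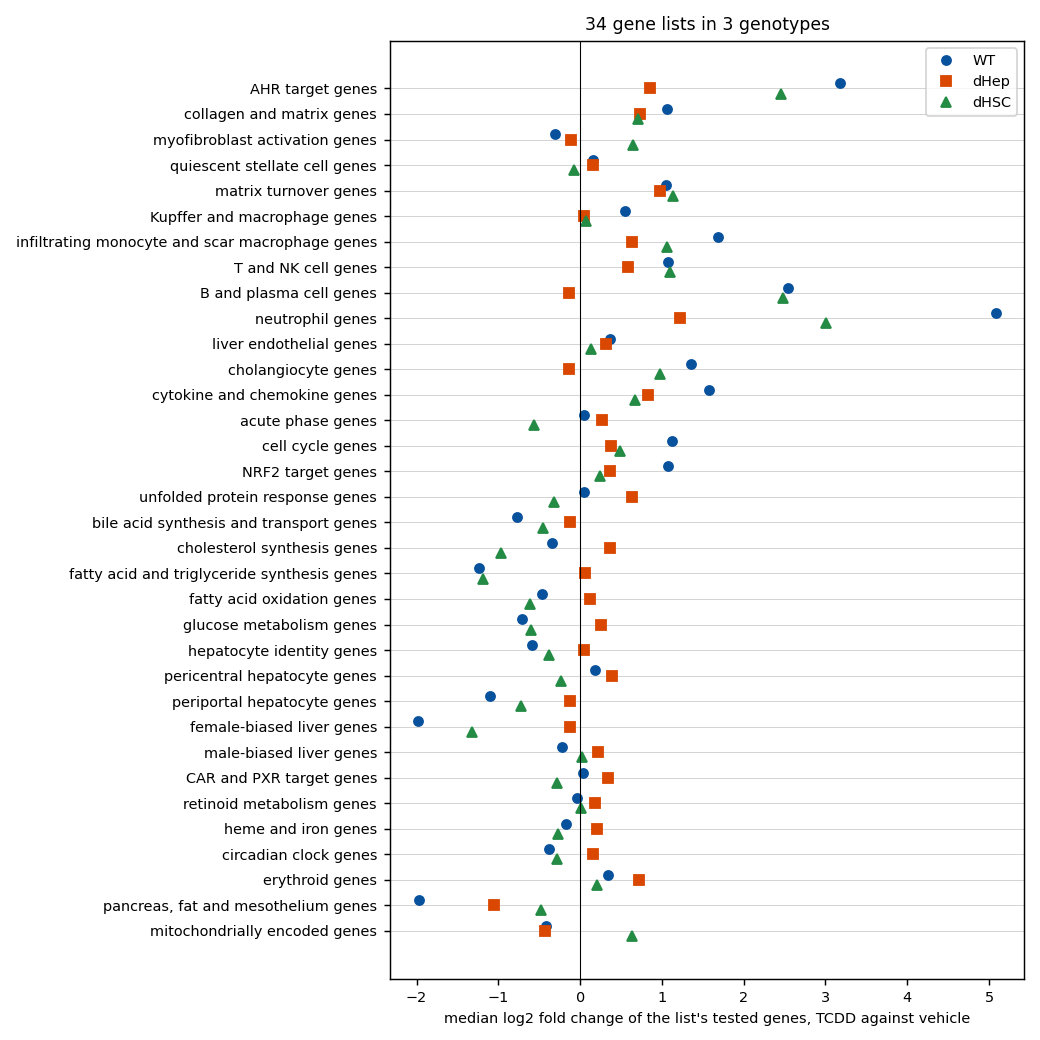
Points are the median log2 change with TCDD over the tested genes of each of 34 lists in WT (circles), dHep (squares) and dHSC (triangles). AHR target genes have medians of 3.17, 0.85 and 2.45, B and plasma cell genes 2.54, -0.14 and 2.48, and collagen and matrix genes 1.06, 0.73 and 0.71.

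Without TCDD, neither deletion was shown to change liver RNA. Against WT in vehicle, edgeR called 0 genes in dHep, where 1025 had an unadjusted p under 0.05 and the smallest adjusted p was 0.623, and DESeq2 called 5, 4 of them higher. In dHSC edgeR called 0 genes, where 220 had an unadjusted p under 0.05 and the smallest adjusted p was 0.444, and DESeq2 called 2, both lower. Adjusted over the list alone, 5 AHR target genes differed in dHep vehicle: Cyp1a1 (2.05 ± 0.69), Cyp1b1 (2.52 ± 0.58) and Ahrr (2.65 ± 0.59) were higher, and Cyp1a2 (-1.73 ± 0.53) and Aldh3a1 lower, all at an adjusted p of 0.623 over all genes. Aldh3a1 had no count in dHep vehicle and in WT vehicle was seen in replicate 1 alone, at 2.24 CPM, so no fold is given. In dHSC vehicle 0 AHR target genes differed. Kupffer and macrophage genes (median 0.35) and cytokine genes (0.44) were higher in dHSC vehicle by camera (adjusted p = 1.86e-06 and 3.83e-06; both adjusted p = 0.675 with an estimated correlation), with 0 members called. Here 2 of the 3 dHep vehicle libraries are among the 5 that stand apart, and 1 of the 3 dHSC vehicle libraries.

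Reads under more than 1 annotated gene were apparently not counted, which lowers the counts of Pdzrn3 (84.7% of exon length under other genes), Tnc (72.6%), Col4a3 (50%), Mmp7 (49.5%), Ovol1 (46.4%), Lnx1 (29.2%), Gipc2 (24.1%) and Lox (20.8%).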

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

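All tests of the patterns weighed here were chosen after the result was seen, except the test of AHR in stellate cells and the counts of other splits, which were written before. The readings of that test and of the test of stellate cell activation were changed, and the test of hepatocytes that kept AHR was replaced, after values were seen.

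A test of the difference between genotypes set apart the TCDD response of 127 genes in dHep from that in WT. Among the 20 named, the log2 difference was 9.39 for Hao1, 8.78 for Sult3a2, 7.56 for Sult3a1, 7.40 for Irx1, 6.28 for Sult2a7, 5.81 for Dsg1c, 5.38 for Cyp2c69, 5.34 for Serpina1e, 5.29 for Mmd2 and 5.03 for Susd4. It was -14.65 for Pnliprp1, -12.32 for Col9a2, -9.32 for Nptx1, -7.73 for Gipc2, -7.41 for Pdzrn3, -7.35 for Col4a3, -6.44 for Cyp1a1, -6.33 for Cyp1b1, -6.33 for Fabp12 and -6.28 for Ahrr. The AHR target list had a median difference of -2.53. Of 40 drawn exchanges of genotype labels, the real one included, 3 called at least as many genes as the real 127, so chance is not excluded for the count. One of the 3, with 194 calls, swaps mice 1 and 15 alone and so stays close to the real one. The highest other, 1492, keeps dHep vehicle replicates 9 and 15 as dHep and relabels dHep TCDD replicate 16 as WT. All 3 then enter the difference with the same sign.

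The first pattern is that 5 libraries stand apart on the first principal component: dHep vehicle replicates 9 and 15, dHep TCDD replicate 16, dHSC vehicle replicate 17 and dHSC TCDD replicate 18. Depth is argued against, since 2 of the other libraries have totals below the median of the 5. An effect of TCDD or genotype on every mouse of a group is argued against, since 0 groups have all 3 libraries among the 5. This count cannot test an effect of genotype on only some mice. Such an effect stays open, since all 5 come from dHep and dHSC and no WT library is among them. Genes with long introns exceeded the highest of the 13 other libraries by at least 0.873 (log2) in replicates 9 and 18, so reads from unspliced RNA or DNA may be part of the cause there. In replicates 15, 16 and 17 the median excess was 0.0114, so an excess like that in replicates 9 and 18 was not seen. The median log2 deviation of the long-intron genes was 0.107, 0.0659 and 0.0363 in these 3. The highest other, WT vehicle replicate 1 with its muscle genes, was at 0.0545, and the next, WT TCDD replicate 2, at -0.000969. A smaller part of unspliced RNA or DNA there stays open. What sets replicates 15, 16 and 17 apart stays open. Mitochondrially encoded genes took 9.86%, 9.85% and 8.70% of their counts, and Neat1 had 832, 490 and 334 CPM. In WT vehicle replicate 7 these were 9.29% and 306 CPM, at a component score of -24.0. Such values are thus not confined to dHep and dHSC. Of the 5 libraries, 4 carry the last 4 mouse numbers, 15 to 18, and a batch that follows mouse number was not tested as the cause.

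The second pattern is that 4 genes, Apol7c, Mmp13, Adamdec1 and Gm8221, rose with TCDD in dHep as in WT. Hepatocytes that kept AHR, as a source in proportion to their share, would keep about the same percent of the increase of every AHR target. The 9 AHR target genes called in WT kept a median of 5.72% of their increase in dHep (75th percentile 7.51%, from 0.380% for Cyp1a2 to 19.3 ± 33.6% (SD, n = 3) for Ugdh). The 4 kept at least 37.1%, or at least 10.4% (Gm8221) less 1 SD. They were picked by their call in dHep, which favours genes that kept much and so inflates their percent. Mmp13 kept 37.1 ± 10.9%, Adamdec1 50.9 ± 17.8% and Apol7c 66.8 ± 29.8% (SD, n = 3). Cyp1a1 kept 3.79 ± 0.40% and Cyp1a2 0.380 ± 0.792%. These values argue against hepatocytes that kept AHR as the main source for Mmp13, Adamdec1 and Apol7c. For Gm8221, at 51.6 ± 41.3%, the spread leaves that source open. Of 97 other genes at least 16-fold higher in WT, 6 also kept at least 37.1% without a call in dHep. Carry-over of RNA is argued against by Col9a2, which kept -0.103% of its increase. AHR in stellate cells stays open: the 4 kept a median of 55.8% in dHSC, above the bound written before, the 25th percentile of 37.0%, but a stellate source of what dHep kept would leave 33.2, 62.9, 49.1 and 48.4% in dHSC, against 57.3, 59.3, 54.3 and 30.8% seen. AHR in other cells, or effects of TCDD without AHR, may account for the rises and were not tested.

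The third pattern is the muscle and contractile genes high in WT vehicle replicate 1. Skeletal muscle genes summed to 174 times and fat genes to 13.8 times the highest of the other 17 libraries, so muscle and fat carried with the liver piece may be the source. Activation of stellate cells in that mouse stays open: the median log2 ratio to WT TCDD mice over 8 stellate cell genes was -0.671, but all 8 were higher than the mean of the other 2 WT vehicle mice, and Thy1 (0.31), Dcn (-0.03) and Pdgfra (-0.17) were near the WT TCDD mean. Whether the carried tissue also holds these 8 genes was not tested, so they cannot tell activation from carry-over.

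For groups of 3 against 3 there are 10 splits, so a share under 0.05 cannot be reached. In fits of the compared groups alone, 1 of 10 splits called as many genes as the real one in WT (751, highest other 0) and 1 of 10 in dHSC (75, highest other 0). In dHep it was 10 of 10 (0 called, highest other 2957), and that other split puts replicates 9, 15 and 16 on one side, which points to the structure of the 5 libraries. In vehicle it was 10 of 10 for dHep against WT (0, highest other 1) and 10 of 10 for dHSC against WT (0, highest other 4). For the dHSC and WT response difference 40 of 40 exchanges called at least as many genes (0, highest other 0). With 0 real calls this share is fixed in advance and tells nothing, here and wherever 10 of 10 is given.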

How the results depend on the processing

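The fits with the percent of counts outside protein-coding genes as a covariate and without the 5 libraries above 2% were chosen after seeing the data. Where a value moved, the cause was not tested unless stated. None of the 5 libraries is from WT. Without them the WT count can therefore move only through the filter, the scaling and the estimate of the spread that all groups share.

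Of 76 results of 44 named genes, 74 kept direction and call with RLE scaling, 76 without a filter, 74 with at least 1 CPM in 3 libraries, 76 with the covariate, 49 without the 5 libraries and 75 with the block of mouse numbers described below. It was 75 of 75 with DESeq2 and 59 of 74 with only the compared groups, where fewer samples estimate the spread. Of 576 values from leaving out 1 library 493 did. No named gene reversed. Of 160 results of the other lists, 81 held with an estimated correlation, 97 with fry and 160 with RLE scaling.

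Without a filter dHep had 19 calls (9 higher, 10 lower). With only the compared groups dHep had 0 (0 and 0) and dHSC 75 (51 and 24). DESeq2 called 1336 in WT (790 and 546), 84 in dHep (42 and 42), 716 in dHSC (450 and 266), 288 for the dHep difference (105 and 183), 3 for the dHSC difference (3 lower), 5 in dHep vehicle (4 and 1) and 2 in dHSC vehicle (2 lower). It shared 33 higher and 17 lower genes between WT and dHep, and 362 and 218 between WT and dHSC. With the covariate there were 1926 calls in WT (1083 and 843), 41 in dHep (33 higher), 792 in dHSC (443 and 349) and 227 for the dHep difference (93 and 134), sharing 32 and 2 between WT and dHep and 389 and 294 between WT and dHSC. Without the 5 libraries there were 1584 in WT (948 and 636), 0 in dHep (0 and 0), 214 in dHSC (146 and 68) and 19 for the dHep difference (3 and 16), sharing 0 higher between WT and dHep and 141 and 62 between WT and dHSC.

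With an estimated correlation the matrix list was at 0.223 in WT, 0.209 in dHep, 0.314 in dHSC and 0.553 for the dHSC difference, and the myofibroblast list at 0.505 in dHep and 0.390 in dHSC. With fry the matrix list was at 0.136 in dHep, 0.112 in dHSC and 0.724 for the dHSC difference, and the myofibroblast list at 0.478 and 0.188 in dHep and dHSC. Fry reversed the myofibroblast (0.939) and male-biased (0.922) lists for the dHep difference, liver endothelial genes in dHSC (0.972) and fatty acid synthesis for the dHSC difference (0.995). The Ahr difference in WT reversed to -0.00661 with RLE and -0.00730 with DESeq2, and in dHep vehicle to 0.0589 with the covariate and 0.142 without the 5 libraries.

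Leaving out 1 library gave 445 to 921 calls in WT (251 to 569 higher, 135 to 352 lower), 0 to 11 in dHep (0 to 6, 0 to 7), 169 to 297 in dHSC (99 to 219, 70 to 93) and 51 to 130 for the dHep difference (21 to 51, 29 to 79). The Ahr change ran from -0.246 to 0.284 in WT and its dHSC difference from -0.0250 to 0.592. The matrix list ran from 0.00361 to 0.959 for the dHep difference and 1.06e-07 to 0.831 for dHSC. The myofibroblast list ran from 0.0142 to 0.738 in WT, 7.86e-08 to 0.498 in dHep, 0.00928 to 0.0827 in dHSC, 0.0967 to 0.936 for the dHep difference and 0.00702 to 0.957 for dHSC.

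The labels pair no mice, but mice 1 to 6, 7 to 12 and 13 to 18 each hold 1 mouse of every group. A fit with these 3 sets as a replicate block was also chosen after seeing the data. Deviations from the group means correlated from -0.623 to 0.732 between mice of one set, so the sets were not taken as pairs. The median was 0.209 within sets and -0.104 between mice of different sets and groups. Of 7776 arrangements of the mice, 838 gave a median within sets at least as high (exact permutation p = 0.108). Own sets correlated best for 9 of 18 mice, against a mean of 6 over the arrangements (exact permutation p = 0.222). The block gave 888 calls in WT, 11 in dHep, 375 in dHSC and 144 for the dHep difference. It ended the call of Adamdec1 in dHep (2.21, adjusted p = 0.0876). It reversed the Ahr difference in WT (-0.0951) and the myofibroblast list for the dHep difference (0.951), and changed no other call of the named genes or of the matrix and myofibroblast lists.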

Other observations

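Against WT, the TCDD response in dHSC was lower for cytokine and chemokine genes (median -0.82, camera adjusted p = 2.00e-10; adjusted p = 0.0728 with an estimated correlation), acute phase genes (-0.40, 4.86e-10; 0.0637 with an estimated correlation) and NRF2 targets (-0.59, 2.87e-07; 0.1102 with an estimated correlation), with 0 members called. Saa1, an acute phase protein, rose by 4.63 in WT and had a difference of -2.82 in dHSC.

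Dbp and Arntl, which peak at opposite times of day, ranged from 0.976 to 157 CPM and from 1.09 to 32.5 CPM over the 18 libraries. Counts on Y-linked genes were at most 1 in any library, and Xist, which has 100% of its exon length under other genes, had 0 counts in all 18.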
